A study of Mus musculus with 8 samples.

How the data were processed

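Liver RNA of male C57BL/6 mice about 20 weeks old was measured in 8 libraries, 4 from mice with free access to food (ad libitum) and 4 from mice fasted for 24 h. Per the labels, mice were co-housed, assigned to groups at random and killed at 10 am, and each stranded total-RNA library was made from 1 µg of DNase-treated RNA. The labels name bcl2fastq 2.17 and BWA as processing tools and mm10 as the genome build. The counting tool, the handling of reads that map to several places and the use of strand are not given in the sources used here.

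The deposited table holds 83057 transcripts of the NONCODE catalogue of long non-coding RNAs, with coordinates, and no gene symbols. Per the file headers it gives raw reads (counts) and RPKM for each library, next to the transcript length in bases, the number of exons and a coding-potential score (CNCI) per transcript, an other-type value that belongs to no library. The counts were used; an empty cell was read as 0, since the deposited RPKM is 0 there. The RPKM values served as a check: reads, length and RPKM give 1 library total each, which equals the sum of the deposited counts in 7 libraries. In ad libitum replicate 3 it exceeds that sum by 19737599 reads, and the cell of the mitochondrial 16S rRNA transcript is empty in that library alone. That transcript took 26.0 to 31.6% of the reads in the libraries, and it was left out of all totals and tests.

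Transcripts were matched by position with bedtools 2.31.1 to GENCODE mouse release 21, which uses the same build. Of the 83057 transcripts, 9742 had the coordinates and exons of a GENCODE transcript. Counts were summed per gene. A protein-coding gene took the transcripts that share exon bases with it on either strand, because opposite-strand pairs of transcripts over the same bases held nearly equal counts, a choice made after the data were seen. A non-coding gene took same-strand transcripts, and its class came from the GENCODE biotype. The value of a coding gene is therefore the signal of non-coding catalogue entries over its exons, not of its full mRNA, and 48.0% of the coding genes with a transcript had at least 1 on the opposite strand. Reads in overlapping transcripts of a gene can be counted more than once. A gene was found for 35.5% of the transcripts, which gave 7357 coding genes, 6247 non-coding genes, 2234 pseudogenes and 2337 other genes. Many liver genes, among them Pck1, G6pc, Fgf21, Angptl4, Pdk4, Igfbp1, Srebf1, Pnpla3, Cyp7a1 and Alb, had no testable transcript and were not analysed here.

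Fasted and ad libitum libraries were compared with edgeR 4.0.16 (quasi-likelihood F test, robust, two-sided) in R 4.3.3, with TMM scaling of the library totals, filterByExpr on the group, and Benjamini-Hochberg adjustment over all genes tested. A gene passed at an adjusted p under 0.05. CPM are counts scaled to the TMM-adjusted library total, and group values are means ± SD of 4 libraries. Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2 and adjusted over the lists with at least 3 tested members, again with an estimated correlation, and with fry. Shares of reads were compared with exact two-sided permutation tests, whose smallest possible p is 0.0286 with 4 against 4 libraries. Percentages of genes passing in 2 classes were compared with Fisher's exact test, which treats genes as independent and does not measure the spread between mice. In a test on simulated data, 200 genes were given changes in counts drawn at the observed spread. Of those changed 2-fold, 53.7% passed, against 8.96% of those changed 1.5-fold and 84.8% of those changed 4-fold, with 5 false calls among 12150 genes. The simulated counts held no technical difference shared by some libraries of a group, so these false calls do not cover one.

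The comparisons, the 49 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Genes are named where they belong to the 10 largest rises or falls among passing genes with at least 1 CPM in the higher group, a symbol other than a predicted-gene, Rik, pseudogene or accession name and no overlap between the groups. They are also named where they belong to the 5 largest rises or falls among non-coding genes by the same criteria, to the up to 3 passing members of lowest p in each list (or the member of largest change where none passed), or to a fixed set of fasting genes. The alternatives were RLE scaling (DESeq2's size factors in edgeR), library totals without TMM, DESeq2 1.42.0, limma-voom, no low-count filter, at least 1 CPM in 4 libraries, the replicate number as a block, and each library left out in turn. After the data were seen, a term for fasted replicates 1 to 3 was added, because these differed in technical measures from the other 5 libraries. It leaves fasted replicate 4 to be compared with the 4 ad libitum libraries, and this lone sample is assumed to vary like the others. The values called those of fasted replicate 4 below come from that model. Counts per transcript instead of per gene, the most abundant transcript of each gene in place of the sum, transcripts that do not overlap, and the choice of 4 transcripts outside genes were also added after the data were seen. Principal components were computed over the 500 most variable genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.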

Results

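Total RNA of mouse liver was sequenced from 4 mice fed ad libitum and 4 mice fasted for 24 h, and the deposited reads per non-coding catalogue transcript were compared between the groups. The question, from the labels, is which transcripts, mainly non-coding ones, differ in liver after a fast. The columns sum to 97163424, 83847332, 51107745 and 98464634 reads in ad libitum replicates 1 to 4 and to 151592176, 169698844, 127621932 and 126365222 reads in fasted replicates 1 to 4. The third ad libitum total lacks the mitochondrial 16S rRNA, which the other totals include. Coordinates are on mm10 and give the gene's span in GENCODE. Values are CPM (read counts scaled to the library total with TMM factors), mean ± SD with n = 4 per group, and every adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless a list test is named.

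Fasted replicates 1 to 3 and fasted replicate 4 did not lie together. On the first principal component, which held 81.6% of the variance, the ad libitum libraries lay between -30.8 and -26.5, fasted replicates 1 to 3 between 42.5 and 45, and fasted replicate 4 at -18.1. Among transcripts with 21 to 200 reads, 16.5 to 17.8% of the counts were odd numbers in fasted replicates 1 to 3, against 9.21 to 10.3% in the ad libitum libraries and 10.8% in fasted replicate 4. No ad libitum library lay with fasted replicates 1 to 3 in either measure. Fasted replicate 4 is therefore also compared with the 4 ad libitum libraries, in a model of all 8 libraries with a term for the other 3 fasted ones. These 3 still enter its filter, scaling and spread, and the lone library adds no spread of its own. Genes named for a low p or for separated groups were chosen with fasted replicate 4 among the 8 libraries. Its agreement for these genes is thus partly selected and is no separate support.

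**Figure D1:**
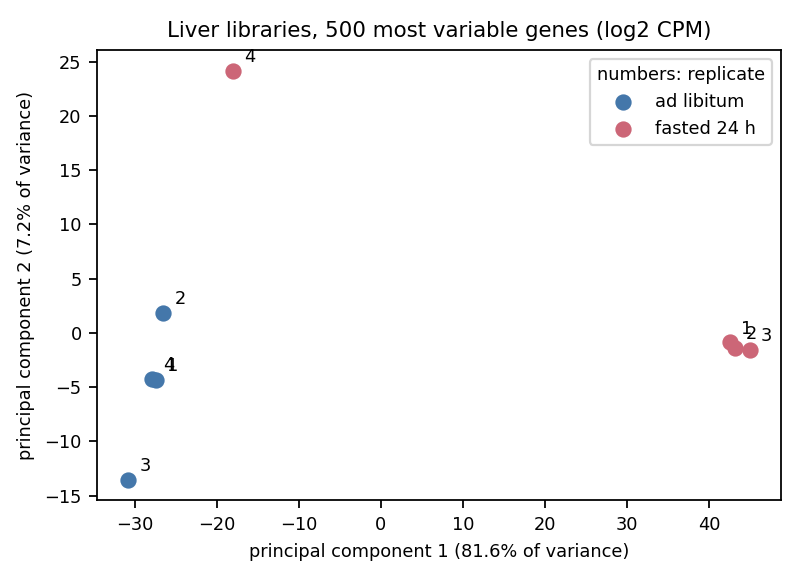
Position of each liver library on the first and second principal component of log2 CPM over the 500 most variable genes, coloured by group, with the replicate number beside each point. Fasted replicates 1 to 3 lie between 42.5 and 45 on the first component and fasted replicate 4 at -18.1, near the ad libitum libraries.

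**Figure D2:**
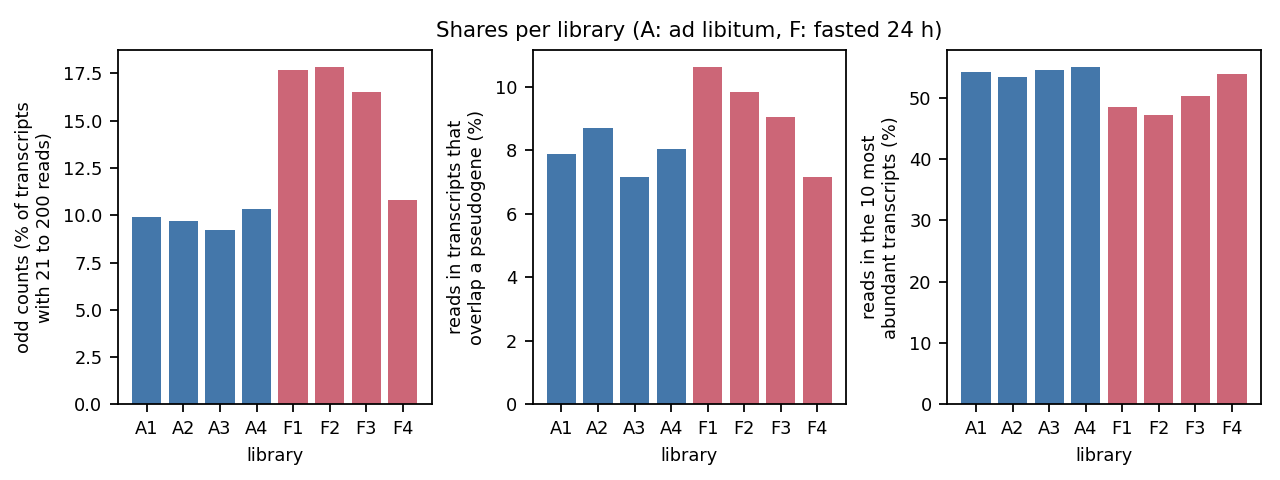
Bars give, for each library, the percentage of odd counts among transcripts with 21 to 200 reads, the percentage of reads in transcripts that overlap a pseudogene and the percentage of reads in the 10 most abundant transcripts. Fasted replicate 4, with 10.8% odd counts, lies near the ad libitum libraries, and fasted replicates 1 to 3 lie at 16.5 to 17.8%.

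Fatty acid breakdown genes were higher in fasted livers, cholesterol synthesis genes were lower, and long non-coding RNAs changed in both directions. With an estimated correlation between genes no gene list passed (camera, lowest adjusted p = 0.32). Only 292 of the 959 list members were tested, so each statement on a list covers its measured members alone. Of 12150 genes tested, 1654 rose and 1372 fell, and 1093 of these changed at least 2-fold (808 up, 285 down). The balance depended on the setting, with 1048 up and 1274 down in limma-voom (367 and 271 at 2-fold) and more falls than rises in 6 of the 8 fits with 1 library left out, such as 881 up and 933 down without ad libitum replicate 1. Among 6014 protein-coding genes 720 rose and 895 fell, and among 3263 non-coding genes 379 rose and 294 fell (272 and 279 with limma-voom). Passing genes made up 26.9% of the coding and 20.6% of the non-coding genes (Fisher's exact test, p = 2.2e-11). That p does not measure the spread between mice, and the 2 classes can share transcripts and were not matched for abundance. Pseudogenes stood apart, with 424 of 1320 rising and 83 falling. They made up 313 of the 808 rises and 24 of the 285 falls of at least 2-fold, and coding genes 229 and 142. In fasted replicate 4 against the ad libitum libraries, 344 genes were higher and 247 lower at the same threshold, 303 of them at least 2-fold. Of the 3026 genes, 540 also passed there in the same direction, a count that shared libraries raise, since the 4 ad libitum libraries and fasted replicate 4 are in both comparisons. That contrast called 326 coding genes, 172 non-coding genes and 50 pseudogenes, and the passing shares of non-coding and coding genes were 5.27% and 5.42% (Fisher's exact test, p = 0.77). Without fasted replicate 4 the counts were 4024 genes, 1640 of them at least 2-fold, 1998 coding and 908 non-coding. The count of genes fell to 1814 without ad libitum replicate 1, 1876 without ad libitum replicate 4, 1846 without fasted replicate 1 and 1811 without fasted replicate 3. The corresponding values at 2-fold were 683 without ad libitum replicate 1, 666 without fasted replicate 1 and 641 without fasted replicate 3. For coding genes they were 1026, 1054, 1061 and 1040 in the order of the 4 libraries above, and for non-coding genes 444 and 434 without fasted replicates 1 and 3.

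Genes of fatty acid oxidation rose. All 6 measured members of the mitochondrial list rose (6 adjusted over the list alone), but 3 of them rose less in fasted replicate 4. As plain log2 differences from the ad libitum mean, Hadha, Slc25a20 and Acsl1 stood there at 0.58, 0.83 and 0.37. In fasted replicates 1 to 3 they stood at 2.19, 2.28 and 1.13. For Cpt1a, Etfa and Eci2 the same differences were 1.71, 1.17 and 0.88 in fasted replicate 4, against 1.85, 0.93 and 0.64. Cpt1a, which makes the acylcarnitines that enter mitochondria (chromosome 19, 3322334 to 3385733), went from 0.363 ± 0.140 to 1.29 ± 0.186 CPM (log2 change 1.81, adjusted p = 7.9e-04). Etfa, a subunit of the electron carrier of acyl-CoA dehydrogenases, rose from 3.08 ± 0.511 to 6.10 ± 0.536 CPM (log2 change 0.98, adjusted p = 5.3e-04). Eci2, an enoyl-CoA isomerase, rose from 38.4 ± 8.11 to 61.7 ± 7.86 CPM (log2 change 0.68, adjusted p = 0.0089). The list had a median log2 change of 1.40 (camera, adjusted p = 3.9e-04), with adjusted p = 0.32 with an estimated correlation and 1.5e-04 to 0.32 over all alternatives. Within fasted replicate 4 the median was 0.85 and 3 members passed. Of 5 measured peroxisomal and other PPARA target genes, 4 rose (5 adjusted over the list alone). Acot3, a peroxisomal acyl-CoA thioesterase (chromosome 12, 84052144 to 84060402), rose from 21 ± 5.52 to 94.0 ± 11.8 CPM (log2 change 2.16, adjusted p = 1.0e-04), read from 5 transcripts that all lie on the opposite strand. Hsd17b4 rose from 2.10 ± 0.351 to 4.50 ± 0.591 CPM (log2 change 1.10, adjusted p = 5.9e-04). The median was 1.30 (camera, adjusted p = 2.1e-04), with adjusted p = 0.32 with an estimated correlation and 4.8e-06 to 0.32 over all alternatives. The median in fasted replicate 4 was 1.16, where 4 members passed with log2 changes of 1.12 for Hsd17b4 and 2.40 for Acot3 among them. Of 3 measured ketone body genes 1 rose (1 up and 1 down adjusted over the list alone), and this was Acat1 (log2 change 0.81, and 0.96 in fasted replicate 4), read from the opposite strand alone. The ketone list as a whole did not pass (camera, adjusted p = 0.51).

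Several measured genes of glucose production rose, and those of nitrogen handling changed in both directions. Of 19 listed gluconeogenesis genes 8 were measured, Pck1 and G6pc not among them. Of these 8 genes 5 rose and none fell (5 adjusted over the list alone). Gpt, which turns alanine into pyruvate, rose from 274 ± 44.0 to 534 ± 104 CPM (log2 change 0.96, adjusted p = 0.0012). Mpc1, a subunit of the mitochondrial pyruvate carrier, rose from 23.9 ± 3.34 to 43.5 ± 5.55 CPM (log2 change 0.86, adjusted p = 5.0e-04). Pcx, pyruvate carboxylase, rose from 0.644 ± 0.132 to 2.09 ± 0.655 CPM (log2 change 1.70, adjusted p = 8.8e-04). Ppargc1a, a transcriptional coactivator of the fasting liver, rose from 1.39 ± 0.528 to 3.17 ± 0.503 CPM (log2 change 1.19, adjusted p = 0.0051). The list passed with a median log2 change of 0.91 (camera, adjusted p = 0.0018), with adjusted p = 0.32 with an estimated correlation and 1.5e-05 to 0.32 over all alternatives, among them 0.06 without fasted replicate 4, which ended the call. The value for fasted replicate 4 was 0.89, and 3 members passed, Gpt at 0.95 and Mpc1 at 0.84 among them, while Pcx stood at 0.96 and Ppargc1a at 1.01 without passing. Of 28 listed genes of amino acid breakdown and the urea cycle 5 were measured, of which 3 rose and 1 fell (3 and 1 adjusted over the list alone). Cps1, which fixes ammonia at the start of the urea cycle (chromosome 1, 67123026 to 67231259), rose from 292 ± 57.1 to 734 ± 77.1 CPM (log2 change 1.33, adjusted p = 9.3e-05). Oat, ornithine aminotransferase (chromosome 7, 132557478 to 132576398), rose from 1.95 ± 0.813 to 11.7 ± 1.75 CPM (log2 change 2.58, adjusted p = 2.2e-04). Glud1, glutamate dehydrogenase, fell from 63.7 ± 10.5 to 22.2 ± 3.28 CPM (log2 change -1.52, adjusted p = 3.8e-05). In fasted replicate 4, which also entered the choice of these 3 genes, the log2 changes were 1.36, 2.79 and -1.25. The list as a whole did not pass (camera, adjusted p = 0.23).

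Sterol synthesis genes fell, and fatty acid synthesis genes changed in both directions. Of 10 measured cholesterol synthesis and SREBP2 target genes 6 fell and none rose (6 adjusted over the list alone). Sc5d, a late enzyme of cholesterol synthesis (chromosome 9, 42251595 to 42264256), fell from 196 ± 20.6 to 56.3 ± 2.99 CPM (log2 change -1.80, adjusted p = 1.6e-06). Stard4, a sterol carrier (chromosome 18, 33199355 to 33213862), fell from 146 ± 19.1 to 43.6 ± 8.62 CPM (log2 change -1.74, adjusted p = 3.6e-05). The median log2 change was -1.34 (camera, adjusted p = 1.7e-05), with adjusted p = 0.32 with an estimated correlation and 8.3e-08 to 0.32 over all alternatives. Fasted replicate 4 alone gave a median of -1.39, and 4 members passed, with -1.91 for Sc5d and -1.84 for Stard4. Of 11 measured fatty acid and triglyceride synthesis genes 3 fell and 2 rose (6 fell and 2 rose adjusted over the list alone). Fasn, fatty acid synthase (chromosome 11, 120805846 to 120824547), fell from 46.2 ± 21.5 to 7.63 ± 2.28 CPM (log2 change -2.60, adjusted p = 0.0049). Acaca, acetyl-CoA carboxylase, fell from 47.8 ± 8.91 to 20.1 ± 2.26 CPM (log2 change -1.25, adjusted p = 8.6e-05). Mid1ip1, a regulator of that carboxylase read from the opposite strand alone, fell from 52.5 ± 13.7 to 8.88 ± 3.27 CPM (log2 change -2.57, adjusted p = 0.0035). Fads2, a desaturase of polyunsaturated fatty acids, rose from 79.5 ± 15.1 to 152 ± 19.7 CPM (log2 change 0.94, adjusted p = 8.3e-04). Scd1 stood at 5635 ± 3681 and 1414 ± 799 CPM in ad libitum and fasted livers (adjusted p = 0.07) and Acly at 5.67 ± 1.63 and 4.34 ± 0.848 CPM (adjusted p = 0.21), and neither passed. The list had a median of -0.63 (camera, adjusted p = 0.044), with adjusted p = 0.57 with an estimated correlation and 0.013 to 0.57 over all alternatives. Its call ended without ad libitum replicate 2 (0.085), without fasted replicate 2 (0.062) or without fasted replicate 4 (0.078), and also without a low-count filter (0.052), at 1 CPM or more in 4 libraries (0.085), with the replicate block (0.062) and with fry (0.05004). Acaca at -1.12 and Fads2 at 0.76 passed in fasted replicate 4, while Fasn at -2.49 and Mid1ip1 at -2.28 did not.

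**Figure D3:**
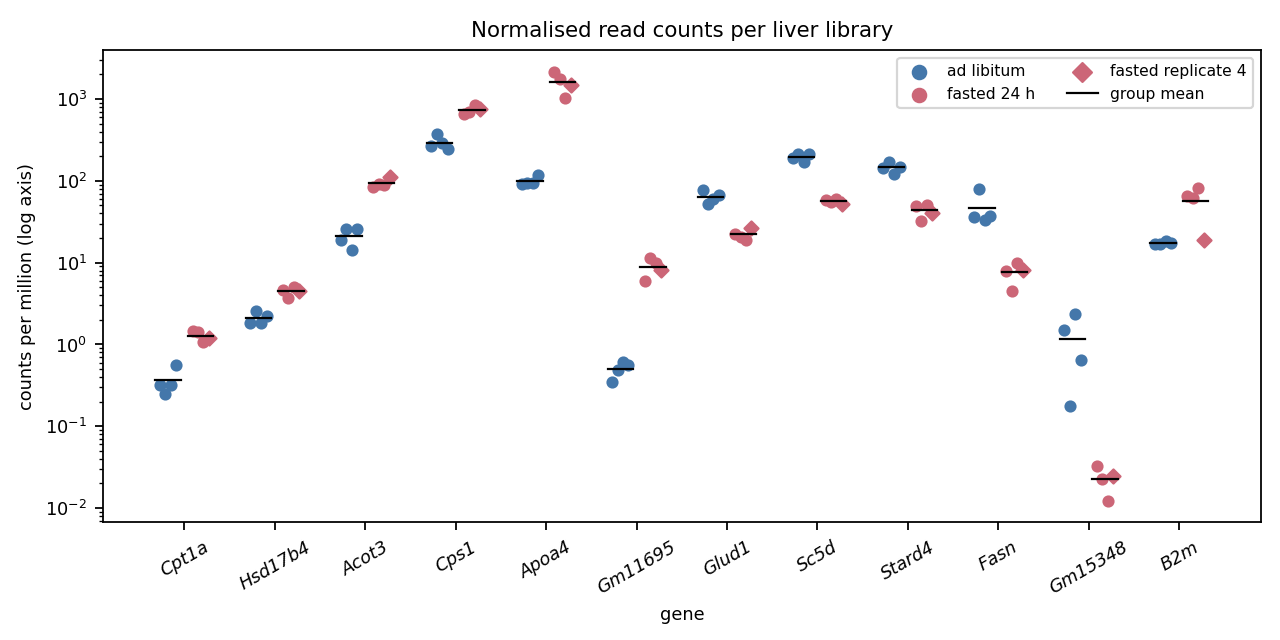
CPM of 12 genes on a log axis, 1 point per library and a line at each group mean, with fasted replicate 4 drawn as a diamond. Fasted replicate 4 lies with the other fasted libraries for Hsd17b4, Cps1, Apoa4, Glud1 and Sc5d, and with the ad libitum libraries for B2m, at 19.1 CPM.

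Lists with weaker calls followed. Of 5 measured lipoprotein genes 2 rose (3 adjusted over the list alone), Apoa4, an apolipoprotein of triglyceride-rich particles (chromosome 9, 46240696 to 46243459), from 99.4 ± 11.6 to 1610 ± 482 CPM (log2 change 4.02, adjusted p = 4.5e-06; 3.90 in fasted replicate 4) and Apoa2 from 1502 ± 268 to 2246 ± 288 CPM (log2 change 0.58, adjusted p = 0.015; 0.34 in fasted replicate 4). Both transcripts read for Apoa4 lie on its opposite strand and 1 of them is Gm10680, and the Apoa2 call ended without ad libitum replicates 1 or 4 (adjusted p 0.055), with 0.0017 to 0.39 over all alternatives. Of 5 ubiquitin-proteasome genes 4 rose (5 adjusted over the list alone), among them Ubb (log2 change 0.72, and 0.40 in fasted replicate 4) and Psmd14 (log2 change 0.56, and 0.31 in fasted replicate 4), and none passed in fasted replicate 4. Of 8 oxidative stress genes 4 rose (4 adjusted over the list alone), with Nqo1, a quinone reductase, at log2 change 0.77, and 1.18 in fasted replicate 4, Txnrd1 at log2 change 0.55, and 0.17 in fasted replicate 4 and Txnip at log2 change 1.07, and 1.12 in fasted replicate 4. Nqo1 and Txnip were read from the opposite strand alone. Of 4 respiratory chain genes 3 rose (3 adjusted over the list alone), Sdhb at log2 change 0.88, and 0.92 in fasted replicate 4 and Atp5b at log2 change 0.59, and 0.48 in fasted replicate 4, while Sdha stood at log2 change 0.73, and -0.01 in fasted replicate 4. The Sdha call ended without ad libitum replicates 1, 3 or 4 or fasted replicates 1, 2 or 3 (adjusted p 0.07 to 0.082) and the Atp5b call without ad libitum replicate 4 (adjusted p 0.051). Sdha also did not pass with library totals (0.063), limma-voom (0.058) or without a low-count filter (0.053), nor Psmd14 with its most abundant transcript (0.14). Of 5 female-biased genes 2 rose (3 adjusted over the list alone), Fmo2 at log2 change 2.30, and 2.11 in fasted replicate 4 and Acot3. The camera adjusted p was 0.017 for lipoproteins, 0.017 for ubiquitin-proteasome, 0.044 for oxidative stress, 0.044 for the respiratory chain and 0.02 for female-biased genes, and for each of these lists adjusted p = 0.32 with an estimated correlation, the highest over the alternatives. The lowest over the alternatives were 0.002, 0.0027, 0.0075, 0.0039 and 0.0044 in the same order. The call ended without fasted replicate 4 (0.071) for lipoproteins, without fasted replicate 4 (0.06) for ubiquitin-proteasome and without fasted replicate 2 (0.054) and without fasted replicate 4 (0.078) for female-biased genes. The same 3 calls also ended without a low-count filter (0.052, 0.052 and 0.067). The respiratory chain call ended without ad libitum replicate 2 (0.085), without ad libitum replicate 4 (0.069) and without fasted replicate 4 (0.071). For oxidative stress it ended without ad libitum replicate 2 (0.099), without ad libitum replicate 3 (0.069), without ad libitum replicate 4 (0.061), without fasted replicate 2 (0.054), without fasted replicate 3 (0.054) and without fasted replicate 4 (0.17), and also without a low-count filter (0.12) and with the replicate block (0.062). Against the ad libitum libraries, fasted replicate 4 gave 0.029, 0.039, 0.012, 0.15 and 0.014 in the order of the list tests above, and with an estimated correlation 0.37 to 0.39.

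The largest changes with separated groups mixed both patterns of fasted replicate 4. Of all tested genes 23.9% had groups that did not overlap, where chance gives 2.86%. Of the 10 largest rises, 8 were read from opposite-strand transcripts alone, namely Apoa4, Retsat, Aqp4, Ralyl, Fth1, Rundc3a, Sema4g and Hmcn2, and of the 10 largest falls 3, namely Efna3, Prg4 and Mid1ip1. Retsat, a retinol saturase, rose from 19.9 ± 5.79 to 169 ± 32.8 CPM (log2 change 3.09, and 2.61 in fasted replicate 4). Aqp4, a water channel, rose from 0.124 ± 0.0374 to 1.89 ± 0.889 CPM (log2 change 3.94, and 2.54 in fasted replicate 4). Ralyl (log2 change 4.67, and 0.75 in fasted replicate 4), Fth1 (log2 change 4.04, and 0.85 in fasted replicate 4), Cerk (log2 change 3.15, and 0.38 in fasted replicate 4), Rundc3a (log2 change 2.64, and 0.74 in fasted replicate 4), Sema4g (log2 change 2.63, and 0.23 in fasted replicate 4) and Hmcn2 (log2 change 2.64, and 1.49 in fasted replicate 4) rose mainly in fasted replicates 1 to 3 and did not pass in fasted replicate 4. The Sema4g call ended without ad libitum replicates 1, 2, 3 or 4 or fasted replicates 1, 2 or 3 (adjusted p 0.057 to 0.07) and the Cerk call without ad libitum replicates 1, 2, 3 or 4 or fasted replicates 1 or 2 (adjusted p 0.054 to 0.069). The Ralyl call ended without ad libitum replicates 1, 2, 3 or 4 (adjusted p 0.053 to 0.058) and the Fth1 call without ad libitum replicates 1, 3 or 4 or fasted replicate 1 (adjusted p 0.052 to 0.065). Efna3, an ephrin ligand (chromosome 3, 89313899 to 89322965), fell from 11.9 ± 8.02 to 0.401 ± 0.0805 CPM (log2 change -4.89, and -5.00 in fasted replicate 4). Slc41a2, a magnesium transporter, fell from 132 ± 50.9 to 21.6 ± 3.97 CPM (log2 change -2.61, and -2.36 in fasted replicate 4). Dpy19l3 fell from 12.2 ± 1.94 to 2.22 ± 0.479 CPM (log2 change -2.46, and -2.13 in fasted replicate 4). Mycn, a proto-oncogene, fell from 1.05 ± 0.326 to 0.160 ± 0.0579 CPM (log2 change -2.73, and -2.40 in fasted replicate 4). Prg4 (-3.07), Atp11a (-2.35), Zbtb7c (-2.25) and Hist1h4d (-2.48), a histone gene whose reads can be split between near-identical copies, completed the falls with Fasn and Mid1ip1. In fasted replicate 4 they stood at -3.23, -2.29, -2.22 and -3.07. Of these falls, those of Dpy19l3, Mycn and Hist1h4d passed there, while Efna3 (adjusted p = 0.12), Slc41a2 (0.11), Prg4 (0.29), Atp11a (0.17) and Zbtb7c (0.24) did not. Among other settings, limma-voom ended the calls of Ralyl (0.31), Fth1 (0.23), Cerk (0.19), Rundc3a (0.079) and Sema4g (0.14), and the replicate block those of Cerk (0.09), Sema4g (0.094), Prg4 (0.066) and Fasn (0.057). The Prg4 call ended without ad libitum replicate 1 or fasted replicates 1 or 2 (adjusted p 0.051 to 0.065).

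Values read for non-coding genes changed as much as those read for the named coding genes, which also come from non-coding catalogue entries. If reads were counted without regard to strand, the antisense genes Gm11695, Gm11967 and Gm15441 may hold the signal of a gene on the other strand. Gm11695, an antisense gene (chromosome 11, 115462045 to 115463454), rose from 0.502 ± 0.113 to 8.83 ± 2.30 CPM (log2 change 4.14, adjusted p = 3.4e-06; 4.02 in fasted replicate 4). The transcript of Gm10680 (chromosome 9, 46242621 to 46243529), which overlaps an exon of Apoa4 on the other strand, is 1 of the 2 read for Apoa4, so both values hold the same signal. It rose from 49.5 ± 6.36 to 799 ± 243 CPM (log2 change 4.01, adjusted p = 9.5e-06; 3.88 in fasted replicate 4). The lincRNA 1700027J07Rik (chromosome 10, 43745809 to 43765836) rose from 0.0723 ± 0.0686 to 1.37 ± 0.406 CPM (log2 change 4.33, adjusted p = 6.8e-04; 4.16 in fasted replicate 4). The lincRNA genes Gm45703 (log2 change 5.86, and 1.44 in fasted replicate 4) and Gm47708 (log2 change 4.26, and 1.91 in fasted replicate 4) rose mainly in fasted replicates 1 to 3, and the Gm45703 call ended without ad libitum replicates 1, 2, 3 or 4 (adjusted p 0.0505 to 0.057). Neither passed with limma-voom (0.37 and 0.095). The lincRNA Gm15348 (chromosome 8, 12706944 to 12719127) fell from 1.17 ± 0.966 to 0.0230 ± 0.00838 CPM (log2 change -5.53, adjusted p = 0.0031). Gm12718 (chromosome 4, 103382500 to 103492040) fell from 1.73 ± 0.855 to 0.0565 ± 0.0434 CPM (log2 change -4.80, adjusted p = 8.3e-04). Gm38416 fell from 9.82 ± 3.09 to 1.10 ± 0.268 CPM (log2 change -3.16, adjusted p = 1.2e-04). The log2 change of 1700027J07Rik was 4.93 without ad libitum replicate 2 and that of Gm12718 -5.55 without fasted replicate 2. Gm36041 and the antisense gene Gm11967 had log2 changes of -2.95 and -2.76. These 5 stood in fasted replicate 4 at -5.47, -5.08, -3.38, -3.34 and -3.07, and Gm38416, Gm36041 and Gm11967 passed. Of 32 measured non-coding RNAs named beforehand from liver or fasting work, 4 rose and 3 fell (4 and 3 adjusted over the list alone). Gm15441, an antisense RNA at Txnip (chromosome 3, 96555765 to 96566801), rose from 17.1 ± 5.77 to 103 ± 26.9 CPM (log2 change 2.60, adjusted p = 0.0015; 2.92 in fasted replicate 4). 4833411C07Rik rose from 11.3 ± 1.74 to 22.2 ± 1.61 CPM (log2 change 0.97, and 1.05 in fasted replicate 4) and 1810008I18Rik fell from 73.2 ± 12.7 to 37.2 ± 2.12 CPM (log2 change -0.97, and -0.93 in fasted replicate 4). The list as a whole did not pass with all 8 libraries (camera, adjusted p = 0.82). In fasted replicate 4 it did, at 0.011, with 0.011 to 0.94 over the alternatives, and with an estimated correlation it did not (adjusted p = 0.25 there).

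Single transcripts, a view added after the data were seen, gave a balance that depended on the setting as well. Of 40840 transcripts tested, 3902 rose and 3131 fell, and 1344 passed in fasted replicate 4 (840 up, 504 down). Of 17281 transcripts outside coding genes, 1883 rose and 1131 fell, and 387 were higher and 202 lower in fasted replicate 4. The balance turned with limma-voom, to 2350 up and 2866 down of all transcripts and 997 up and 1048 down outside coding genes. Without a low-count filter 11275 and 5922 passed, at 1 CPM or more in 4 libraries 1659 outside coding genes, and with library totals 4661 of all transcripts. Without fasted replicate 4 the counts were 11295 and 5579. Without fasted replicate 1, fasted replicate 3 or ad libitum replicate 4 they fell to 4158, 4195 and 4588 of all transcripts and to 1700, 1719 and 2004 of those outside coding genes. Transcripts in no GENCODE gene that passed both with all 8 libraries and in fasted replicate 4, with separated groups and at least 1 CPM, numbered 194 up and 94 down. The transcript with the largest rise among them lies on chromosome 19 from 17311324 to 17312203, 13938 bases from Gcnt1, and rose from 0.0986 ± 0.0561 to 2.49 ± 0.856 CPM (log2 change 4.69, adjusted p = 1.4e-05). That with the largest fall lies on chromosome 18 from 75813568 to 75817132, 3046 bases from Zbtb7c, and fell from 4.85 ± 2.11 to 0.135 ± 0.0166 CPM (log2 change -5.13, adjusted p = 4.4e-06). The next rise lay on chromosome 16, 9292 bases from Ciita (log2 change 4.41, and 1.20 in fasted replicate 4), and the next fall on chromosome 8, 4892 bases from Osgin1 (-4.27, and -5.41 in fasted replicate 4).

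Markers of other cell types took small shares of the reads. These shares count only catalogue transcripts at the marker genes, from 1 neutrophil gene to 12 stellate cell genes per list. The hepatocyte secreted and identity genes themselves took 0.470% in ad libitum livers, so a small share does not measure how many cells of a type were present. Of 16 shares tested, 3 had the smallest exact permutation p possible, 0.0286, and none passed after adjustment (0.15). An adjusted p under 0.05 would need most of the 16 shares to reach that smallest p. The adjusted values therefore do not argue against a difference in these 3 shares. The adipocyte marker share went from 0.0196 ± 0.0161% to 0.00558 ± 0.00190%, most of it from Car3, a carbonic anhydrase at 194 ± 163 and 52.6 ± 17.5 CPM (adjusted p = 0.072). Without ad libitum replicate 2 the ad libitum mean was 0.0118%, and the ratio of fasted to ad libitum share 0.474 in place of 0.284, with a log2 change of -1.12 for Car3 in place of -1.88. The hepatocyte secreted and identity genes went from 0.470 ± 0.0326% to 0.331 ± 0.0218% (Ttr, transthyretin, fell from 64.6 ± 4.81 to 26.5 ± 1.29 CPM; log2 change -1.29, adjusted p = 4.0e-06, and -1.27 in fasted replicate 4), and the periportal markers from 0.556 ± 0.0254% to 0.471 ± 0.0291%. Serpina1c, read from 2 opposite-strand transcripts and with reads that can be split between the Serpina1 copies, belongs to both lists, held most of both shares and fell from 4577 ± 363 to 3213 ± 383 CPM (log2 change -0.51, and -0.31 in fasted replicate 4). By number, 3 of 7 hepatocyte and 3 of 5 periportal genes rose, so the 2 share falls are mainly those of Serpina1c. The 3 shares in fasted replicate 4 were 0.00288%, 0.338% and 0.467%. Mitochondrial transcripts other than 16S rRNA took 9.92 ± 0.742% and 10.8 ± 1.66% of the reads in ad libitum and fasted libraries (exact permutation p = 0.37, adjusted 0.49), and the 10 most abundant transcripts 54.3 ± 0.701% and 49.9 ± 2.89% (exact permutation p = 0.057, adjusted 0.23). Stellate cell and muscle marker shares went from 0.00424 ± 8.21e-04% to 0.00732 ± 0.00235% and from 4.03e-05 ± 2.06e-05% to 1.08e-04 ± 7.27e-05% and did not pass (exact permutation p = 0.086 for each, adjusted 0.23). In fasted replicate 4 they were 0.00388% and 3.44e-05%, against means of 0.00847% and 1.32e-04% in fasted replicates 1 to 3, a difference without a test.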

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

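The strand test, both pseudogene measures and the splits of transcript counts were chosen only after the result was seen. The splits of gene counts were chosen before the data were examined. The 3 tests on fasted replicate 4 address a pattern seen in the data, and their predictions were written before their own results.

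Fasted replicate 4 stood apart from fasted replicates 1 to 3, at -18.1 on the first principal component (the others at 42.5 to 45) and 24.2 on the second (the others at -1.56 to -0.88). A weaker fasting response in that mouse and a library of an ad libitum mouse with a wrong label both predict that its fatty acid genes lie near the ad libitum level. Positions were set on a scale from the ad libitum mean at 0 to the mean of fasted replicates 1 to 3 at 1. Over 16 such genes the median position of fasted replicate 4 was 0.893 (95% bootstrap interval 0.733 to 1.05). The interval rests on 1 library and cannot show the spread between mice. Without fasted replicate 1, 2 or 3 in the scale the median was 1.11, 0.976 or 0.966. These values argue against a wrong label and against a weaker response of these genes as a whole. They do not argue against a weaker response of Hadha (0.267), Acsl1 (0.329) and Slc25a20 (0.362), singled out after their values were seen. Sequence present in several copies, counted differently in fasted replicates 1 to 3, was taken to predict an excess of multi-copy transcripts there. The excess was -0.15 log2 (95% bootstrap interval -0.19 to -0.09) over 586 multi-copy and 2135 single-copy transcripts identical to a GENCODE transcript. Reads moved between copies would raise some copies and lower others, so this median cannot decide the question. What sets fasted replicates 1 to 3 apart, with 16.5 to 17.8% odd counts, stays open, and because it holds 3 of 4 fasted libraries and no ad libitum library, changes seen in these 3 alone and a further effect of fasting cannot be told apart.

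Pseudogenes rose in fasted replicates 1 to 3, with 672 higher and 127 lower of 1438 tested without fasted replicate 4, against 22 and 28 of 1320 in fasted replicate 4 alone. Gm14020, for example, went from 0.154 ± 0.0391 to 43.8 ± 0.442 CPM (n = 3) with 0.124 CPM in fasted replicate 4, and Fth-ps2 from 1.73 to 61.9 CPM with 1.88 CPM, both singled out after their values were seen. Of the 672, 556 were also tested with all 8 libraries, and over these the median position of fasted replicate 4 was 0.0312, which restates the pattern and is no separate test of a rise by fasting itself. Pseudogenes with exon-junction sequence of a coding gene, where reads of spliced transcripts could be placed, lay below all others by -0.22 log2 (95% bootstrap interval -0.37 to -0.07). Their median was 0.20, against 0.63 for 482 with other coding sequence and 0.10 for 184 with none, so reads of coding genes placed at copies stay possible and the cause is open.

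Of the 105 coding genes chosen by the naming rule, 36 were read from opposite-strand transcripts alone, 8 of the 10 largest rises among them, so no separate value of their own strand exists. If reads were counted without regard to strand, opposite-strand transcripts over the same bases would hold equal counts. Over 26 such pairs the median absolute log2 ratio was 0.0929, against 0.177 for 89 pairs on 1 strand, in line with counting without strand, so antisense signal at a coding gene may be the signal of the gene itself.

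Chance was tested with all 35 splits of the 8 libraries into 4 and 4. The real split gave 3026 genes, 1093 at least 2-fold, 673 non-coding and 1615 coding genes, 7033 transcripts and 3014 outside coding genes. For each of these 1 of 35 splits, the real one, reached the count, the highest other giving 0 at an adjusted p under 0.05 with edgeR. Every other split mixes fasted and ad libitum libraries. At an unadjusted p under 0.05 with edgeR the real split of gene counts gave 4517 genes, and the other splits a median of 270 and at most 2139. Chance alone is thus unlikely for these counts, within what 35 splits can show, but fasted replicates 1 to 3 are together in the real split.

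Single libraries far from the other 3 of their group were found in 20 of 288 groups examined, where chance gives 14.4. For fasted replicate 4 these were Acta2 (0.222 CPM), Alas1 (1.14), Etfa (6.89), Hnf4a (32.2), Stat5b (15.2) and the pericentral marker share (0.0380%). Ad libitum replicate 2 stood out for Acaca (61.1 CPM), Fasn (78.4) and the B cell marker share (4.08e-04%). Ad libitum replicate 4 stood out for Apoa4 (116.8 CPM), Gm10680 (59.0), Bhlhe40 (0.610) and Slc27a5 (63.8). Others were Oat in ad libitum replicate 1 (3.16 CPM), Rundc3a in ad libitum replicate 3 (1.89), Arntl in fasted replicate 2 (2.27) and the neutrophil marker share in ad libitum replicate 3 (3.91e-06%) and fasted replicate 2 (8.37e-07%), which rests on 1 gene.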

How the results depend on the processing

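The term for fasted replicates 1 to 3, the most abundant transcript of each gene, the list tests under other low-count filters and all alternatives of transcript counts were chosen only after the result was seen. Except where values are given, the gene counts stayed within 1.5 times under RLE scaling, library totals, DESeq2, limma-voom, both filters, the most abundant transcript of each gene and the replicate block (2286 genes with the block). With the term, 591 genes passed, 303 at least 2-fold, 172 non-coding, 326 coding and 39 of the 120 named ones (108 with all 8 libraries). Genes changed at least 2-fold numbered 638 with limma-voom and 573 at 1 CPM or more in 4 libraries, and coding genes 1029 with library totals. Leaving out 1 library gave 1811 (without fasted replicate 3) to 4024 genes (without fasted replicate 4), 641 to 1640 at least 2-fold, 434 to 908 non-coding and 1026 (without ad libitum replicate 1) to 1998 coding genes, by the same fasted libraries unless named. Of transcripts, 7033 passed (3014 outside coding genes), 11275 (5922) without a low-count filter, 4661 with library totals, 1659 outside coding genes at 1 CPM, 1344 (589) with the term and 4158 (1700) to 11295 (5579) with 1 library left out. Scaling moved the median log2 change of all genes by little, from 0.00 to 0.02. Of the gene lists, 10 passed with camera, 6 without a low-count filter, 0 with an estimated correlation (lowest adjusted p 0.32, 5 at an unadjusted p under 0.05), 18 with fry, which tests whether any members changed in 1 direction without regard to other genes, 14 with the term, and 3 (without fasted replicate 4) to 10 with 1 library left out. Under the term H2-K1, Sdha and Stab2 went to -0.0776, -0.0115 and -0.27 on the log2 scale, against rises with all libraries. Of the other values of single named genes under alternatives, 1715 kept their side of the threshold, 281 no longer passed and 12 newly passed. Of those of single lists the numbers were 626, 37 and 18. Not all that kept their side kept their direction, since 37 results that did not pass had another sign under an alternative. Of 69 passing named genes that did not pass under the term, 20 also had less than 0.5 times their log2 change there, and the cause was not tested. Of the shares of reads, 3 of 16 had p under 0.05, and 4 without mitochondrial transcripts and transcripts without a gene. With 1 library left out only differences of shares were computed; these and the shares without mitochondrial transcripts moved by less than 1 SD in 181 cases and by more in 13. The pseudocount alternatives, meant for normalised values, were not run.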

Other observations

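The values of fasted replicate 4 and those of the most abundant transcript in place of the sum were chosen only after the result was seen. The other tests in this part were not.

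Other gene groups moved in part. Of 5 measured glycogen genes 3 fell and 1 rose (3 and 1 adjusted over the list alone), with Ppp1r3b, which targets a phosphatase to glycogen, falling from 349 ± 48.4 to 163 ± 15.6 CPM (log2 change -1.10, and -1.20 in fasted replicate 4). The glycogen list did not pass with all 8 libraries (camera, adjusted p = 0.11). Of 3 male-biased genes 2 fell (2 adjusted over the list alone), Cyp2u1 at log2 change -1.05, and -0.85 in fasted replicate 4 and Cspg5 at log2 change -1.15, and -0.60 in fasted replicate 4 (camera, adjusted p = 0.058). Of 11 autophagy and lysosome genes 6 rose and 2 fell (6 and 3 adjusted over the list alone), with Gabarapl1 at log2 change 0.55, and 0.35 in fasted replicate 4 and Atg9b at log2 change -1.70, and -1.17 in fasted replicate 4 (camera, adjusted p = 0.26). Of 9 growth hormone and IGF axis genes 2 fell (2 adjusted over the list alone), Stat5b at log2 change -0.58, and -0.44 in fasted replicate 4 and Onecut1 at log2 change -1.51, and -2.03 in fasted replicate 4, and Igf1 stood at 57.5 ± 4.84 and 56.8 ± 8.47 CPM (adjusted p = 0.93; camera for the list, adjusted p = 0.36). Mki67, a marker of dividing cells, fell from 5.79 ± 1.53 to 1.70 ± 0.243 CPM (log2 change -1.76, and -1.87 in fasted replicate 4), the 1 of 3 cell cycle genes that passed. Nr3c1, the glucocorticoid receptor, fell from 45.4 ± 2.02 to 30.2 ± 3.13 CPM (log2 change -0.59, and -0.42 in fasted replicate 4), while Fkbp5, a glucocorticoid target, rose from 10.7 ± 2.65 to 17.1 ± 1.93 CPM (log2 change 0.67, and 0.70 in fasted replicate 4), among 3 rising and 2 falling of 7 glucocorticoid genes (camera, adjusted p = 0.89, with a median of -0.12 and a mean of 0.17).

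The remaining lists did not pass with camera and all 8 libraries, at adjusted p from 0.15 to 0.98, and the counts adjusted over the list alone differed from those given by 1 more gene rising for insulin, glycolysis and bile acids, 1 more falling for erythroid and platelet genes, and 1 more each way for ribosome biogenesis. Genes moved both ways, with 2 up and 2 down of 9 insulin and FOXO1 genes (Irs2 up, Sesn3 down), 2 and 1 of 10 circadian clock genes (Arntl and Cry2 up, Bhlhe40 down), 1 and 1 of 10 ribosome biogenesis genes (Wdr43 up, Wdr12 down), and 1 and 2 of 6 glycolysis genes (Tpi1 up, Khk and Pfkfb3 down). Marker lists gave 3 and 2 of 7 hepatocyte identity genes (Hnf4a up), 3 and 1 of 5 periportal genes (Hsd17b13 up), 1 and 2 of 7 pericentral genes (Lgr5 and Tbx3 down) and 2 and 2 of 9 stellate cell genes (Acta2 up, Lrat and Col1a1 down). Genes only rose in bile acid synthesis and transport (2 of 4, Abcb4 and Slc27a5), xenobiotic metabolism (2 of 4, Nqo1 and Alas1), antigen presentation (2 of 5, B2m and H2-K1), heat shock proteins (1 of 5, Hspa8), T and NK cells (1 of 6, Trac) and endothelium (1 of 7, Stab2). Genes only fell among endoplasmic reticulum chaperones (2 of 5, Sel1l and Syvn1), histones (2 of 4, Hist1h4d and Hist2h2aa1, whose reads can be split between copies) and interferon genes (1 of 6, Ifih1). None passed among 5 integrated stress response genes (Vldlr largest, 1.13) and 5 acute phase genes (Hamp2, 1.25). The same held for 7 small structural RNAs (Snord17, 0.47), 4 B cell genes (Blk, -0.67), 3 cholangiocyte genes (Spp1, -1.46), 3 adipocyte genes (Car3, -1.88) and 3 gallbladder, gut and mesothelial genes (Upk3b, -0.60). Too few members were tested for camera in 6 lists, with 1 passing of 2 muscle genes (Ckm, 2.20) and 1 of 2 mitochondrially encoded genes (mt-Nd6, 0.42), 0 of 2 Kupffer cell genes (Cd163, -0.64) and 0 of 2 erythroid and platelet genes (Itga2b, -0.84), 1 neutrophil gene measured but not tested, and none measured of the exocrine pancreas list. Fasted replicate 4 alone gave calls for endoplasmic reticulum chaperones (down, camera adjusted p = 0.0041), glycogen (down, 0.046), acute phase (down, 0.046) and periportal genes (up, 0.046). With an estimated correlation these were 0.25, 0.47, 0.47 and 0.43. In fasted replicate 4 B2m, Acta2, Ckm, Trac, Stab2, Alas1 and Slc27a5 stood at 0.13, 0.31, 0.54, 0.02, -0.27, 0.02 and 0.04, against 1.70, 2.76, 2.20, 1.33, 1.33, 0.80 and 0.56 with all libraries.

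Some of these calls ended when 1 library was left out, given here with the library and the adjusted p without it. This held for Acta2 (ad libitum 1, 2 or 4, 0.051 to 0.061), Alas1 (ad libitum 2, 3 or 4 or fasted 1, 2 or 3, 0.068 to 0.089), Arntl (ad libitum 1, 2 or 4 or fasted 1, 2 or 3, 0.072 to 0.14), B2m (ad libitum 1, 2, 3 or 4 or fasted 1, 2 or 3, 0.068 to 0.075), Bhlhe40 (ad libitum 1, 2 or 3 or fasted 1 or 2, 0.072 to 0.11) and Ckm (ad libitum 1, 2 or 4, 0.054 to 0.059). It also held for Col1a1 (ad libitum 1, 3 or 4 or fasted 1, 2 or 3, 0.059 to 0.099), Cry2 (ad libitum 1, 2 or 4 or fasted 1 or 3, 0.07 to 0.1), Cspg5 (ad libitum 1 or 4 or fasted 3, 0.054 to 0.067), H2-K1 (ad libitum 1, 2, 3 or 4 or fasted 1, 2 or 3, 0.067 to 0.12), Hist2h2aa1 (ad libitum 1, 3 or 4 or fasted 1, 2 or 3, 0.073 to 0.13), Ifih1 (ad libitum 1, 3 or 4 or fasted 1, 2 or 3, 0.065 to 0.096), Lrat (fasted 1 or 2, 0.061 to 0.063) and Onecut1 (ad libitum 1, 2 or 3 or fasted 1, 3 or 4, 0.051 to 0.074). Further such genes were Pfkfb3 (ad libitum 1 or 2 or fasted 3 or 4, 0.061 to 0.07), Slc27a5 (ad libitum 1, 2, 3 or 4 or fasted 1, 2 or 3, 0.058 to 0.094), Stab2 (ad libitum 1, 2, 3 or 4 or fasted 1, 2 or 3, 0.056 to 0.096), Tbx3 (ad libitum 1, 3 or 4 or fasted 1, 2 or 3, 0.069 to 0.13), Trac (ad libitum 1, 2 or 3 or fasted 1, 2 or 3, 0.056 to 0.086), Wdr12 (ad libitum 1, 3 or 4 or fasted 1 or 3, 0.0504 to 0.083) and mt-Nd6 (ad libitum 1, 2, 3 or 4 or fasted 2, 3 or 4, 0.051 to 0.15). Among other settings, limma-voom ended the calls of Acta2 (0.15), Alas1 (0.062), B2m (0.075), Ckm (0.084), Cry2 (0.06), H2-K1 (0.092), Hist2h2aa1 (0.052), Slc27a5 (0.063), Stab2 (0.15) and Trac (0.086). Library totals ended those of Arntl (0.078), Cry2 (0.052), H2-K1 (0.074), Hist2h2aa1 (0.061), Ifih1 (0.087), Onecut1 (0.086), Tbx3 (0.063), Wdr12 (0.084) and mt-Nd6 (0.055), and RLE scaling that of mt-Nd6 (0.052). The replicate block ended those of Alas1 (0.053), Arntl (0.078), B2m (0.1), Bhlhe40 (0.11), H2-K1 (0.063), Ifih1 (0.054), Khk (0.063), Pfkfb3 (0.063), Stab2 (0.083), Tbx3 (0.065), Trac (0.075), Wdr12 (0.051) and mt-Nd6 (0.075). The use of no low-count filter ended those of Bhlhe40 (0.057), H2-K1 (0.066), Pfkfb3 (0.061) and Stab2 (0.052), and the most abundant transcript in place of the sum those of Alas1 (0.057), Arntl (0.084), Bhlhe40 (0.19), Hist2h2aa1 (0.051), Stab2 (0.12) and Tbx3 (0.12). The log2 change of Ckm was 1.61 without fasted replicate 3, that of Car3 -1.12 without ad libitum replicate 2 and that of Spp1 -0.72 without ad libitum replicate 3. Among the genes of this part, Acta2, Bhlhe40, Blk, Cd163, Ckm, Gabarapl1, H2-K1, Hamp2, Hist2h2aa1, Hnf4a, Irs2, Itga2b, Lgr5, Mki67, Nqo1, Slc27a5, Stab2, Syvn1 and Tbx3 were read from opposite-strand transcripts alone.

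Transcripts outside coding genes may follow the coding gene beside them. Pairs of a passing transcript and a passing coding gene at most 10 kb away numbered 177, with 119 genes among them. Of these pairs 82.5% changed in 1 direction. This was above the 95th percentile of 57.6% in 10000 random pairings, none of which reached the observed share. All 35 such pairs found in fasted replicate 4 shared a direction (95th percentile of random pairings 71.4%). Several pairs can share 1 gene and are then not independent. Both comparisons hold fasted replicate 4 and the ad libitum libraries, so the second is no separate support. Unannotated exons of the neighbouring gene and counting without strand were not separated from a link between the transcripts.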
